A study of Homo sapiens with 24 samples.

How the data were processed

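Gene expression was measured in 24 samples of established human dental pulp stem cells exposed to ethanol at 0, 1, 5, 10, 20 or 50 mM for 24 or 48 h. Per the labels' protocols, total RNA was extracted with a commercial kit, labelled with biotin and hybridised, and the series design names the Affymetrix human genome U133 Plus 2.0 array. The deposited values are intensities on a linear scale, 1 per probe set and array, that the authors made with MAS5, per the submitters' processing notes. The version of MAS5, the scanner and the detection calls are not given in the sources used here. The values themselves show the scaling: the mean of each array without the lowest and highest 2% of its 54675 probe sets was 500.07 or 500.08. No array was left out, and no genome build is given in the sources used here, so positions are not printed.

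Samples were put in groups by dose and time from their titles, 12 groups of 2. The values were used as deposited and converted to log2 with no offset. MAS5 combines the probe pairs of a probe set on each array by itself, so dim probe sets are noisy on the log2 scale, and changes of dim genes carry larger errors.

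Probe sets were named from the platform annotation. Of the probe sets 62 were controls, 41091 had 1 gene symbol, 1801 had several symbols and 11721 had none, and only those with 1 symbol were used for named genes. Symbols were matched to a reference gene table through the gene identifier, which changed 0 of them. XIST, TSIX and Y-linked genes, 59 probe sets, were left out of all tables, and other transcripts of the X-inactivation region were kept. Each of the 19740 remaining genes was represented by the probe set with the highest mean log2 signal over all 24 arrays. Genes were tested where that mean exceeded the median of the means of all probe sets, a mean log2 signal of 6.07 or a signal of 67.3, which left 12178 genes.

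All genes were fitted in R 4.3.3 with limma 3.58.1. A model with a mean per group was fitted to all 24 arrays, so that the groups shared 1 estimate of the spread with 12 residual degrees of freedom. Variances were moderated with eBayes with a trend on the mean signal, which added 7.61 prior degrees of freedom at the median gene. The median residual SD was 0.14 log2. A gene was called where the Benjamini-Hochberg adjusted p lay under 0.05 over all genes tested in that comparison. The 16 comparisons were each dose against untreated cells of the same time, the dose trend at each time, the difference between the trends, the mean of the 5 doses against untreated cells, and 48 h against 24 h in untreated cells and over all doses. Dose trends used scores of log2(dose + 1) and are given as the fitted change from 0 to 50 mM. Departure from a trend was tested with the remaining differences between the 6 doses of a time in the same model. With 2 arrays per group, the number of arrays limits the precision.

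Gene lists were tested with camera at a preset correlation between genes of 0.01, and beside it with camera at an estimated correlation and with fry, each adjusted over the lists of a comparison. The 40 lists held 1054 entries, of which 966 matched a gene on the array and 88 did not. The 38 lists with at least 5 tested genes were tested, and the endothelial and leukocyte lists, with 4 and 3 tested genes, were not.

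The groups, tests, filters, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, in each main comparison, up to 10 of the largest rises and 10 of the largest falls among called genes, up to 4 members with the smallest p of each list that was called or had a called member, and a fixed set around histone demethylation, mineralization, ethanol oxidation and stress. The single doses and the difference of trends lay outside the rule, and the genes named there were chosen after their values were seen. A list of 66 very long mRNAs was written after the 24 h result had been seen, and 54 of these genes outside that result were tested.

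The fit was tested on simulated data, in which 67 of the 12178 genes were changed by 0.5 log2, 67 by 1 and 66 by 2. For 50 mM against untreated cells at 48 h it recovered 40.3% of changes of 0.5 log2, 77.6% of 1 log2 and 95.5% of 2 log2, with 9 false calls, 5.96% of the calls. For the dose trend at 48 h it recovered 64.2%, 86.6% and 100%, with 7 false calls, 4.02% of the calls, and with no change it made 0 calls. A simulated shift of the 29 unfolded protein and integrated stress genes by -0.1 log2 gave a camera adjusted p of 1.228e-04 for the 48 h trend, a shift of 0 gave 0.497, and 0 other lists were called. The simulated genes varied independently of each other. The simulation therefore cannot show how often camera at the preset correlation calls lists whose genes vary together.

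Alternatives to these settings were quantile normalization, median centring of each array over all its probe sets, and no filter. A filter at the 70th percentile or on the highest group mean and an offset of 5.21 (the 10th percentile of the signal) before log2 were also run. Others were the mean of all probe sets of a gene, each probe set by itself, the replicate number as a block and eBayes without a trend. Array weights, other dose scores, fits to the arrays of 1 time or to the untreated arrays, and leaving out each array in turn followed. The mean of all probe sets weighs dim and bright probe sets alike. A call lost with it can reflect noise of dim probe sets as well as probe sets that disagree. For pairs of doses that share untreated arrays, 100 unchanged groups were simulated. Splits of the arrays or of whole groups and orders of the doses were drawn 100 times, and all 36 choices of 1 group per time as the untreated one were run.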

Results

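The series asked what ethanol does to gene expression in human dental pulp stem cells, an established culture of mesenchymal stem cells from the soft core of the tooth that can be driven to form mineralizing, odontoblast-like cells. Cells received 0, 1, 5, 10, 20 or 50 mM ethanol for 24 or 48 h, and total RNA was hybridised to a whole-genome oligonucleotide array. The 6 doses and both times made 12 groups of 2 arrays, 24 arrays in all. The treatment note in the labels stops at 20 mM, whereas the design text and the sample titles also name 50 mM, and groups were taken from the titles. Of 19740 genes with a named probe set, 12178 were bright enough to be tested. The labels do not say whether the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

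The arrays were separated more by time than by ethanol. The first principal component of the tested genes held 22.1% of the variance and lay between -17.8 and -13.2 on the 24 h arrays and between 11.6 and 18.5 on the 48 h arrays, while the next component held 6.74%. Over all probe sets, the 2 arrays of a group correlated at r = 0.897 to 0.924, and arrays of different doses at the same time at r = 0.890 to 0.921. The ratio of the 3' to the 5' control probe sets of beta-actin, a sign of RNA integrity, ranged from 1.60 to 3.28 between arrays. It averaged 2.40 ± 0.07 (SD, n = 2) in untreated cells at 24 h, 1.80 ± 0.28 at 1 mM, 1.99 ± 0.01 at 5 mM, 1.84 ± 0.27 at 10 mM, 2.46 ± 0.25 at 20 mM and 2.46 ± 0.06 at 50 mM. At 48 h it averaged 2.62 ± 0.60 in untreated cells, 1.98 ± 0.40 at 1 mM, 1.88 ± 0.08 at 5 mM, 2.17 ± 0.06 at 10 mM, 2.51 ± 0.28 at 20 mM and 2.67 ± 0.86 at 50 mM. The same ratio for GAPDH averaged 0.94 ± 0.05 in untreated cells at 24 h and 0.85 to 0.96 at the doses. At 48 h it was highest in untreated cells, at 1.01 ± 0.01, against 0.90 to 0.97 at the doses and 0.91 ± 0.01 at 50 mM. Whether this difference bears on the 48 h comparisons was not tested.

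At 24 h each dose of ethanol was compared with the untreated cells of that time. Cathepsin Z (CTSZ), a lysosomal carboxypeptidase, was higher at every dose, by 0.95 ± 0.08 log2 (SE, n = 2 arrays per group) at 1 mM and 0.88 ± 0.08 at 50 mM. Lamin B1 (LMNB1), a protein of the nuclear lamina, was higher by 0.79 ± 0.10 at 1 mM and 0.78 ± 0.10 at 50 mM. The receptor tyrosine phosphatase PTPRO fell by 0.70 at 1 mM and by 0.64 at 50 mM, and PSIP1, a chromatin-binding transcription coactivator, fell by 0.47 and 0.49. In total 17 genes were higher at all 5 doses and 2 genes, PTPRO and PSIP1, were lower at all 5. Of the 17 genes 11 were higher at every dose with median centring, 12 with eBayes without a trend, 3 with the mean of all probe sets, and 10 without either replicate of the untreated cells at 24 h. No gene was lower at all 5 doses with median centring, eBayes without a trend or the mean of all probe sets. PTPRO did not pass at 1 or 50 mM with median centring, nor did PSIP1. The 17 included AHNAK (0.74 at 1 mM and 0.78 at 50 mM), dystonin (DST, 0.53 and 0.54), MACF1 (0.54 and 0.53) and nesprin-2 (SYNE2, 0.78 and 0.77). These genes were singled out after their values were seen, because they passed at every dose. All 5 doses shared the same 2 untreated arrays. In 100 simulations of unchanged groups against shared controls 0 genes passed at every dose (limma), with 0.068 calls per dose on average. The simulated arrays varied independently, so the simulation cannot show whether both untreated arrays deviated together. The mean of the 17 genes lay -0.62 log2 from its mean over all arrays on each untreated array at 24 h, between -0.04 and 0.16 on the other 24 h arrays, and at -0.21 and -0.18 on the untreated arrays at 48 h. The actin ratio of those untreated arrays lay within the range of the treated ones. A further 54 genes of a list of very long mRNAs, written after the 24 h result had been seen, had a median of 0.19 for the mean of the 5 doses at 24 h, against 0.66 for the 17 genes. With the mean of all probe sets, which weighs dim and bright ones alike, CTSZ was at -0.05 at 50 mM. AHNAK and MACF1 were at -1.24 and -0.02 at 1 mM. The other CTSZ probe set was dim, with a mean log2 signal of 6.18 against 12.1 for the one used. The other AHNAK probe sets lay between 4.17 and 8.81, against 13.9. Noise of dim probe sets and disagreement cannot be told apart in the means of CTSZ and MACF1. Over both times, the AHNAK probe set at 8.81 was at -0.05 for the mean of the 5 doses (unadjusted p = 0.392 by limma). The AHNAK probe set used was at 0.53 in that comparison (unadjusted p = 1.548e-12 by limma), so these AHNAK probe sets disagreed. How much noise of the dimmer ones adds to the AHNAK means cannot be told. DST and PSIP1 did not pass with the mean of all probe sets at 1 or 50 mM. Of 213 values past the threshold that are named for these and the other comparisons, 105 stayed past it in the same direction with that mean, 87 did not and 21 were no longer tested.

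**Figure D1:**
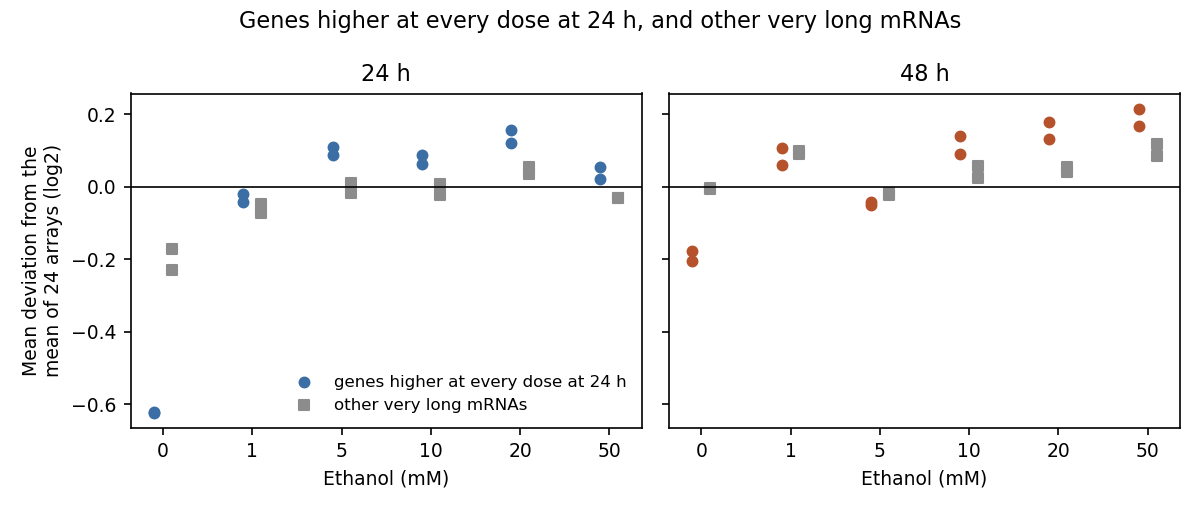
Mean deviation from the mean of 24 arrays (y axis, log2) of the 17 genes higher at every dose at 24 h (circles) and of 54 other very long mRNAs (grey squares), on each array by ethanol dose (x axis, mM), at 24 h (left) and 48 h (right). The untreated 24 h arrays, on which the 17 genes were chosen, lay at -0.62 for these genes and at -0.17 and -0.23 for the other mRNAs.

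The number of genes that differed at 24 h did not follow the dose. At 1 mM 58 genes passed, 52 higher and 6 lower, at 5 mM 104 (75 higher, 29 lower), at 10 mM 80 (63 and 17), at 20 mM 211 (134 and 77) and at 50 mM 80 (64 and 16). Centring each array on the median of all its probe sets moved the middle of the tested genes by 0.12, 0.15 and 0.11 log2 at 1, 5 and 50 mM. Without centring that middle lay at -0.013, -0.015 and 0.0032. The median signal was 88.2 and 76.2 on the untreated arrays at 24 h, near the filter cut of 67.3, so dim probe sets set this shift. Centring gave splits of 48 higher and 0 lower at 1 mM, 120 and 2 at 5 mM, 27 and 3 at 10 mM, 28 and 29 at 20 mM and 52 and 2 at 50 mM. In the order of the doses, eBayes without a trend gave 30, 49, 44, 99 and 36 genes, and the mean of all probe sets 12, 22, 16, 97 and 20. Genes of the unfolded protein and integrated stress responses stood higher at 10 mM, where 4 of 29 rose and none fell, 9 and 0 adjusted over the list alone (camera adjusted p = 1.291e-05, and adjusted p = 0.0133 with an estimated correlation). Their examples at 10 mM were the amino acid enzymes ASNS (0.68 ± 0.09) and PSAT1 (0.79 ± 0.15) and the mTOR inhibitor DDIT4 (0.82 ± 0.11). At 20 mM the same list was again higher, with 3 rising and 2 falling, 8 and 2 adjusted over the list alone (adjusted p = 0.00141, and adjusted p = 0.0302 with an estimated correlation). The list was not called at 5 mM (median 0.03, adjusted p = 0.405) or at 50 mM (median 0.05, adjusted p = 0.557). At 1 mM it was called (median 0.07, no member past the threshold over all genes or over the list alone, adjusted p = 0.0314) but not with an estimated correlation (adjusted p = 0.2025). That call also ended with the mean of all probe sets, with quantile normalization, without replicate 1 of the untreated cells and without replicate 1 or 2 of 1 mM. ASNS and PSAT1 did not pass at 10 mM with the mean of all probe sets, and PSAT1 did not with eBayes without a trend. Mitotic genes were lower at 20 mM, where 5 of 32 fell and none rose, 11 and 1 adjusted over the list alone (adjusted p = 4.737e-09, and adjusted p = 0.00115 with an estimated correlation), among them cyclin B1 (CCNB1), which fell by 0.27 but did not pass with the mean of all probe sets or median centring. DNA replication genes were lower there too, with 5 of 31 falling, 9 adjusted over the list alone (adjusted p = 3.291e-07, and adjusted p = 0.00115 with an estimated correlation), for instance MCM3, which fell by 0.48 but did not pass with median centring or eBayes without a trend. Splicing genes were lower at 20 mM with 3 of 32 falling and 1 rising, 7 and 3 adjusted over the list alone (adjusted p = 0.00374, and adjusted p = 0.0410 with an estimated correlation). The splicing call ended with the mean of all probe sets (adjusted p = 0.0693) and without replicate 2 of the untreated cells or of 20 mM (adjusted p = 0.0531 and 0.0854). The mitotic list did not keep 1 direction over the doses. At 5 mM the mitotic list was called higher (median 0.093; none past the threshold over all genes, 3 higher adjusted over the list alone; adjusted p = 8.130e-04, and adjusted p = 0.0589 with an estimated correlation). At 10 mM it was called lower (median -0.083; none past the threshold over all genes or over the list alone; adjusted p = 0.0083, and adjusted p = 0.149 with an estimated correlation). Leaving out 1 array moved these counts: without replicate 1 of the untreated cells at 24 h, 29 genes passed at 1 mM, 42 at 5 mM, 38 at 10 mM, 78 at 20 mM and 36 at 50 mM. Without replicate 1 or 2 of the treated group itself, 42 or 37 passed at 5 mM and 26 or 30 at 10 mM, 91 passed at 20 mM without its replicate 2, and 20 at 50 mM without its replicate 2.

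**Figure D2:**
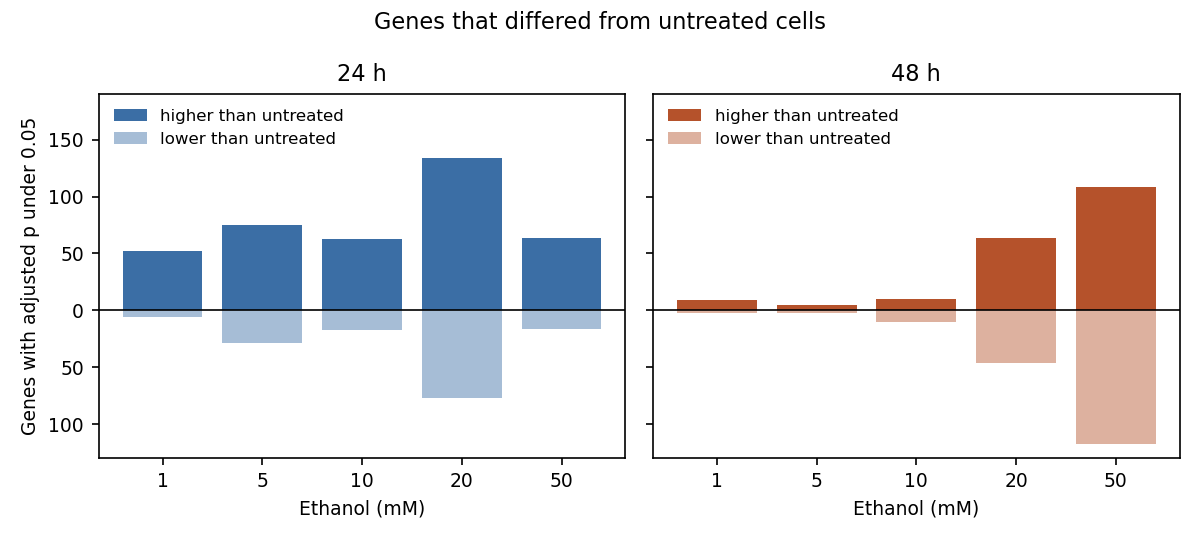
Number of genes (y axis) with an adjusted p under 0.05 in each ethanol dose (x axis, mM) against untreated cells of the same time, at 24 h (left) and 48 h (right). Bars above 0 are genes higher than in untreated cells and pale bars below 0 are genes lower; at 24 h the highest count was 211 at 20 mM, and at 48 h the counts were 11, 7, 20, 110 and 225 in the order of the doses.

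At 50 mM for 24 h, 80 genes differed from untreated cells. Matrix Gla protein (MGP), an inhibitor of calcification, showed the largest rise, at 2.73 ± 0.43 log2 (SE, n = 2 arrays per group), a 6.65-fold increase with an adjusted p of 0.00247 by limma. It was followed by the imprinted antisense transcript KCNQ1OT1 (1.66 ± 0.34), the Rab GTPase RASEF (1.05 ± 0.13), the endocytic receptor LRP1 (1.01 ± 0.11), the matrix protein hemicentin-1 (HMCN1, 0.89 ± 0.10) and the long noncoding RNA FTX (0.84 ± 0.08). POLM, a DNA repair polymerase, fell by 2.68, and the sorting nexin SNX11 fell by 1.17. SOCS3, an inhibitor of cytokine signalling, fell by 0.44, and the heparan sulfate sulfatase SULF1 by 0.43. Among 35 genes of the extracellular matrix 7 rose and none fell, 9 and 0 adjusted over the list alone. Fibrillin-2 (FBN2) rose by 0.38 ± 0.05, fibrillin-1 (FBN1) by 0.35 ± 0.06 and the collagen chains COL6A2 and COL8A1 by 0.41 ± 0.07 and 0.35 ± 0.06. The matrix list was called higher (camera adjusted p = 6.297e-09) but not with an estimated correlation, where the adjusted p was 0.120. Smooth muscle and pericyte genes (median 0.13 over 17) and ribosomal protein genes (median 0.12 over 25) had no member past the threshold over all genes, and 5 higher and 1 lower against 0 adjusted over the list alone. Both were called by camera (adjusted p = 0.0051 and 2.662e-04) and neither with an estimated correlation (adjusted p = 0.120 and 0.576). The smooth muscle call also ended with the mean of all probe sets (median 0.04, camera adjusted p = 0.780). At 10 mM ribosomal protein genes were called lower (median -0.18, 17 of 25 lower adjusted over the list alone and none over all genes; adjusted p = 2.995e-12, and adjusted p = 0.381 with an estimated correlation). Quantile normalization turned that median to 0.0093. The osteogenic genes SLC20A1, a phosphate transporter, and periostin (POSTN) rose by 0.33 ± 0.06 and 0.34 ± 0.06, and the homeobox gene LHX8 fell by 0.33, whereas at 50 mM for 48 h it rose. Of the 26 values named for 50 mM at 24 h, 4 kept their call with the mean of all probe sets, 4 were not tested and 18 lost it. RASEF moved to 0.26, FTX to 0.53, FBN2 to 0.14, POSTN to 0.09 and SNX11 to -0.59, and COL6A2 and SOCS3 also did not pass. LRP1 (1.19), COL8A1 (0.76) and SLC20A1 (0.35) did not pass either, though their values were larger. POLM and LHX8 kept their values, and only their adjusted p changed (0.071 and 0.073 by limma). Median centring ended 7 of the 26 calls, those of KDM2A, LHX8, PSIP1, PTPRO, SLC20A1, SOCS3 and SULF1. Without a trend in eBayes 10 ended, those of KCNQ1OT1, POLM, SNX11, COL6A2, POSTN, KDM2A, LHX8, PSIP1, PTPRO and SOCS3.

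The dose trend at 24 h asked which genes changed steadily with log2(dose + 1), and its values are the fitted change from 0 to 50 mM. FTX rose by 1.01 ± 0.07 log2 (SE, 12 arrays), RASEF by 0.86 ± 0.11, LRP1 by 0.84 ± 0.09, HMCN1 by 0.78 ± 0.08 and the transcription factor ZBTB20 by 0.74 ± 0.06. The basement membrane proteoglycan perlecan (HSPG2) rose by 0.67 ± 0.09, the ribosome assembly ATPase MDN1 by 0.65 ± 0.10 and the histone methyltransferase KMT2D by 0.38 ± 0.07. PTPRO fell by 0.58, PSIP1 by 0.44, the endoplasmic reticulum chaperone HSP90B1 by 0.34 and the RNA-binding protein HNRNPA2B1 by 0.29. In all 42 genes passed, 34 higher and 8 lower. Of those named, FTX, RASEF, LRP1, HMCN1 and ZBTB20 were among the 17 genes higher at every dose, and PTPRO and PSIP1 were lower at every dose. A step from the 2 shared untreated arrays to all doses can give such a trend without a change from dose to dose. The extracellular matrix list was higher (2 of 35 rose, FBN2 by 0.25 ± 0.04 and versican, VCAN, by 0.32 ± 0.06; 6 rose and 1 fell adjusted over the list alone), with camera adjusted p = 0.00239 and adjusted p = 0.314 with an estimated correlation. At single doses the matrix list was called higher at 1 mM (median 0.08; 4 of 35 rose, 8 adjusted over the list alone; adjusted p = 4.923e-06, and adjusted p = 0.2025 with an estimated correlation). At 10 mM it was called lower (median -0.15; none past the threshold over all genes, 3 higher and 11 lower adjusted over the list alone; adjusted p = 0.0192, and adjusted p = 0.481 with an estimated correlation). The 10 mM call of the matrix list ended with the mean of all probe sets (median -0.06, camera adjusted p = 0.915). The mitotic list was lower over the trend (median -0.11, no member past the threshold over all genes, 2 lower adjusted over the list alone). Its camera adjusted p was 0.00239, and 0.116 with an estimated correlation. Many dose differences at 24 h were not steady: 507 genes departed from the trend, among them 27 of the 42 that passed it. The count was 22 without replicate 1 of the untreated cells at 24 h, 23 without replicate 2 of 50 mM and 68 without replicate 1 of 50 mM. It was 20 with median centring, 25 with eBayes without a trend, 21 with the mean of all probe sets and 7 with linear dose scores. Of the 14 values named, 2 kept their call with the mean of all probe sets, 2 were not tested and 10 lost it. These were RASEF (0.21), PSIP1 (-0.07), VCAN (0.17), LRP1, HSPG2, ZBTB20, FBN2, KMT2D, HSP90B1 and HNRNPA2B1. LRP1, HSPG2, FBN2, KMT2D, HSP90B1 and HNRNPA2B1 had larger changes with that mean than without it. Median centring and eBayes without a trend ended 6 each, in both cases FBN2, VCAN, HSP90B1, HNRNPA2B1 and PSIP1, with KMT2D in the first and PTPRO in the second. When the 6 groups at 24 h were put in other orders, 56 of 100 orders, the order of the doses included, gave at least 42 genes.

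At 48 h more genes passed at 20 and 50 mM than at the lower doses. CTSZ, LMNB1, JUN, a subunit of the transcription factor AP-1, and PPP3R1, the regulatory subunit of the phosphatase calcineurin, were higher at all 5 doses. Of these 4 genes CTSZ alone was so with median centring, with eBayes without a trend and without replicate 1 of the untreated cells at 48 h. CTSZ was higher by 0.62 ± 0.08 log2 at 1 mM, 1.39 ± 0.08 at 10 mM and 1.79 ± 0.08 at 20 mM (SE, n = 2 arrays per group). With the mean of all its probe sets CTSZ was at -0.02 at 1 mM and did not pass at 10 or 20 mM, nor did MALAT1 at 10 mM, which eBayes without a trend ended as well. Heme oxygenase 1 (HMOX1), an enzyme of the oxidative stress response, was higher by 0.36 ± 0.07 at 1 mM, 0.56 ± 0.07 at 10 mM and 0.82 ± 0.07 at 20 mM. Its value of 0.31 ± 0.07 at 5 mM did not pass (adjusted p = 0.0969 by limma), and that at 1 mM did not with median centring or eBayes without a trend. The nuclear noncoding RNA MALAT1 fell by 0.66 at 10 mM and by 1.34 at 20 mM. At 1 mM 11 genes passed (9 higher, 2 lower), at 5 mM 7 (5 and 2), at 10 mM 20 (10 and 10), at 20 mM 110 (64 and 46) and at 50 mM 225 (108 and 117). With median centring the splits were 4 higher and 3 lower at 5 mM, 7 and 2 at 10 mM, 39 and 15 at 20 mM, and 25 and 38 at 50 mM. With eBayes without a trend 3, 12, 71 and 122 genes passed at 1, 10, 20 and 50 mM. With the mean of all probe sets the split turned to 49 higher and 87 lower at 20 mM, and at 50 mM 66 of 199 genes were higher. With each probe set by itself it was 215 higher and 421 lower at 20 mM and 297 and 662 at 50 mM. Between 20 and 50 mM 37 higher and 36 lower genes were shared, against 0.568 and 0.442 for independent lists. Both doses share the untreated arrays, and lists as long as these from 100 simulations of unchanged groups shared 11.9 and 9.65 genes on average, at most 21 and 15. Part of the excess may still come from the shared arrays. Mitotic genes were lower at 1 mM (adjusted p = 1.684e-09, and adjusted p = 0.00185 with an estimated correlation; none past the threshold over all genes, 7 lower adjusted over the list alone). Smooth muscle and pericyte genes were lower at 1 mM as well (1 of 17 fell, 2 adjusted over the list alone, adjusted p = 1.032e-04, and adjusted p = 0.0216 with an estimated correlation). The smooth muscle call ended with the mean of all probe sets (adjusted p = 0.756). Mitotic genes were lower also at 10 mM (1 of 32 fell, 5 adjusted over the list alone, adjusted p = 1.020e-10, and adjusted p = 0.00105 with an estimated correlation). At 20 mM their median was -0.11 with no member past the threshold, over all genes or over the list alone (adjusted p = 0.0171, and adjusted p = 0.163 with an estimated correlation). Without replicate 1 of 20 mM that median was 1.841e-04. The unfolded protein and integrated stress list was called lower at 20 mM (2 of 29 fell, 3 adjusted over the list alone, adjusted p = 0.00857) but not with an estimated correlation (adjusted p = 0.0867). It ended with the mean of all probe sets and without replicate 1 of 20 mM. Without replicate 1 of the untreated cells at 48 h, 70 genes passed at 20 mM. At 1 mM the split turned to 3 higher and 6 lower without its replicate 1 and to 3 and 14 without its replicate 2. It had 7 genes without replicate 1 or 2 of 10 mM at 24 h, replicate 1 of 50 mM at 24 h, or replicate 1 or 2 of 50 mM at 48 h. At 5 mM the split turned to 4 higher and 14 lower without its replicate 2.

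At 50 mM for 48 h, 225 genes differed from untreated cells, 108 higher and 117 lower. CALML4, a calmodulin-like protein, rose by 1.65 ± 0.35 log2 (SE, n = 2 arrays per group), CTSZ by 1.48 ± 0.08, the peroxisomal and mitochondrial protein MPV17L by 1.43 ± 0.31, LMNB1 by 1.17 ± 0.10 and the F-box protein FBXL17 by 1.07 ± 0.12. The mitochondrial fission protein MTFP1 fell by 2.37, the transcription factor ZBED6 by 1.36, the noncoding RNA SNHG24 by 1.34, the CREB3 regulator CREBRF by 0.95, MALAT1 by 0.90, the anaphase-promoting complex subunit CDC27 by 0.88 and the craniofacial transcription factor TRPS1 by 0.86. Over the 48 h trend 11 of the 12 MALAT1 probe sets were lower, with changes between -2.26 and 0.03. In the unfolded protein and integrated stress list 4 of 29 genes fell and none rose, both over all genes and adjusted over the list alone. They were HSP90B1 (fell by 0.60), ASNS (fell by 0.54) and the serine synthesis enzymes PSAT1 and PHGDH (fell by 0.78 and 0.51); the list was lower with camera adjusted p = 1.394e-04, and adjusted p = 0.0236 with an estimated correlation. Of the oxidative stress list HMOX1 (0.51 ± 0.07) and the metallothionein MT1X (0.43 ± 0.09) rose and thioredoxin reductase (TXNRD1) fell by 0.25, and another metallothionein, MT1H, rose by 0.89 ± 0.14. Immediate early genes JUN, KLF10 and IER2 rose by 0.53 ± 0.07, 0.40 ± 0.08 and 0.39 ± 0.09. The membrane protease MMP14 and the growth factor receptor PDGFRB rose by 0.39 ± 0.08 and 0.40 ± 0.08, and the proapoptotic gene PMAIP1 fell by 0.58. LHX8, which fell at 50 mM for 24 h, rose by 0.39 ± 0.07. Camera also called the mitotic list higher (median 0.08, adjusted p = 0.0479), the heat shock list higher (median 0.11, adjusted p = 0.0490) and the smooth muscle list lower (median -0.10, adjusted p = 0.0280), each with no member past the threshold over all genes. Adjusted over the list alone, 1 mitotic and 2 heat shock genes were higher and 3 smooth muscle genes lower. With an estimated correlation these 3 calls were lost (adjusted p = 0.181, 0.151 and 0.151). With the mean of all probe sets the median of the smooth muscle list turned to 0.05, and the mitotic and heat shock calls ended. The 108 higher and 117 lower genes became 24 and 38 without replicate 1 of 50 mM at 48 h, fewer than at 20 mM, and 32 and 70 without its replicate 2. Without replicates 1 and 2 of the untreated cells they became 76 and 43 or 62 and 53, and quantile normalization gave 131 and 127. Median centring gave 25 and 38, 63 genes in all, and eBayes without a trend 122. Median centring ended 10 of the 28 calls named, those of KLF10, IER2, MMP14, PDGFRB, PMAIP1, MT1X, PHGDH, TXNRD1, KDM3A and LHX8. Without a trend in eBayes those of IER2, MMP14, MT1X, TXNRD1 and KDM3A ended. Of the 28 values, 13 kept their call with the mean of all probe sets, 2 were not tested and 13 lost it. CTSZ moved to 0.46, FBXL17 to 0.24, PMAIP1 to -0.13, CDC27 to -0.23, CREBRF to -0.42, JUN to 0.31, TRPS1 to -0.55 and TXNRD1 to -1.78. ASNS, HSP90B1 and MMP14 had larger changes, of -0.93, -0.70 and 0.52, but did not pass, nor did MPV17L.

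The dose trend at 48 h gave more genes than the trend at 24 h, 391 in all, 210 higher and 181 lower. The CTSZ trend from 0 to 50 mM was 1.64 ± 0.07 log2 (SE, 12 arrays), 3.12-fold, with an adjusted p of 1.141e-11 by limma. The LMNB1 trend was 1.09 ± 0.09, 2.13-fold. These are fitted changes: measured against untreated cells, CTSZ was at 1.79 at 20 mM and at 1.48 at 50 mM. HMOX1 and MALAT1 also changed less at 50 mM than at 20 mM. With the mean of all CTSZ probe sets the CTSZ trend was 0.71 and did not pass. The other, dim CTSZ probe set had a trend of -0.22 (unadjusted p = 0.742 by limma). HMOX1 rose by 0.58 ± 0.06, MT1X by 0.45 ± 0.08, MT1H by 0.84 ± 0.12, MMP14 by 0.51 ± 0.07, PDGFRB by 0.43 ± 0.07, and the notch pathway transcription factor RBPJ by 0.48 ± 0.08. MALAT1 fell by 1.17, ZBED6 by 1.27, CDC27 by 0.94, the secretory pathway protein CNST by 0.92, CREBRF by 0.86, TRPS1 by 0.83 and PMAIP1 by 0.55. In the unfolded protein and integrated stress list HSP90B1 fell by 0.57, ASNS by 0.57 and PSAT1 by 0.80, 3 of 29 falling and none rising, and 8 lower and 1 higher adjusted over the list alone. The list was lower with camera adjusted p = 1.382e-05, and adjusted p = 0.0109 with an estimated correlation. Genes of oxidative phosphorylation were higher, with 4 of 29 rising (9 adjusted over the list alone), among them the complex I subunits NDUFA1 (0.28 ± 0.07) and NDUFA2 (0.25 ± 0.06). Heat shock genes (1 of 13 rose, the mitochondrial cochaperonin HSPE1 by 0.28 ± 0.07; 2 adjusted over the list alone) and mitotic genes (1 of 32 rose, CCNB1 by 0.20 ± 0.05; 2 adjusted over the list alone) were higher as lists. These 3 lists had camera adjusted p = 0.00409, 0.00722 and 0.0349, and adjusted p = 0.361, 0.0635 and 0.195 with an estimated correlation. With the mean of all probe sets the 3 calls ended (camera adjusted p = 0.107, 0.494 and 0.494). The mitotic list did not rise steadily: its medians against untreated cells were -0.17, 0.01, -0.14, -0.11 and 0.08 in the order of the doses. Among the immediate early genes JUN rose by 0.44 ± 0.06, IER2 by 0.42 ± 0.08 and KLF10 by 0.30 ± 0.07, and LHX8 rose by 0.29 ± 0.06. NDUFA1, NDUFA2 and HSPE1 did not pass with median centring or with eBayes without a trend, and CCNB1, KLF10 and LHX8 did not with median centring. Departures from the trend were fewer than at 24 h, in 41 genes. The split of the 391 genes turned to 143 higher and 221 lower with the mean of all probe sets and to 469 and 892 with each probe set by itself. Median centring gave 123 genes, 67 higher and 56 lower, and eBayes without a trend 254. Of the 27 values named 19 kept their call with the mean of all probe sets, 1 was not tested and 7 lost it. Among the 7 were CTSZ, PMAIP1 (-0.22), RBPJ (0.18), CCNB1, ASNS and NDUFA2. ASNS and NDUFA2 had larger changes with that mean than without it. The split turned to 71 and 84 or 105 and 122 without replicates 1 or 2 of 50 mM at 48 h, and 236 genes passed without replicate 2 of the untreated cells. Of 100 orders of the 6 groups at 48 h, 8, the order of the doses included, gave at least 391 genes, and the highest count was 414.

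**Figure D3:**
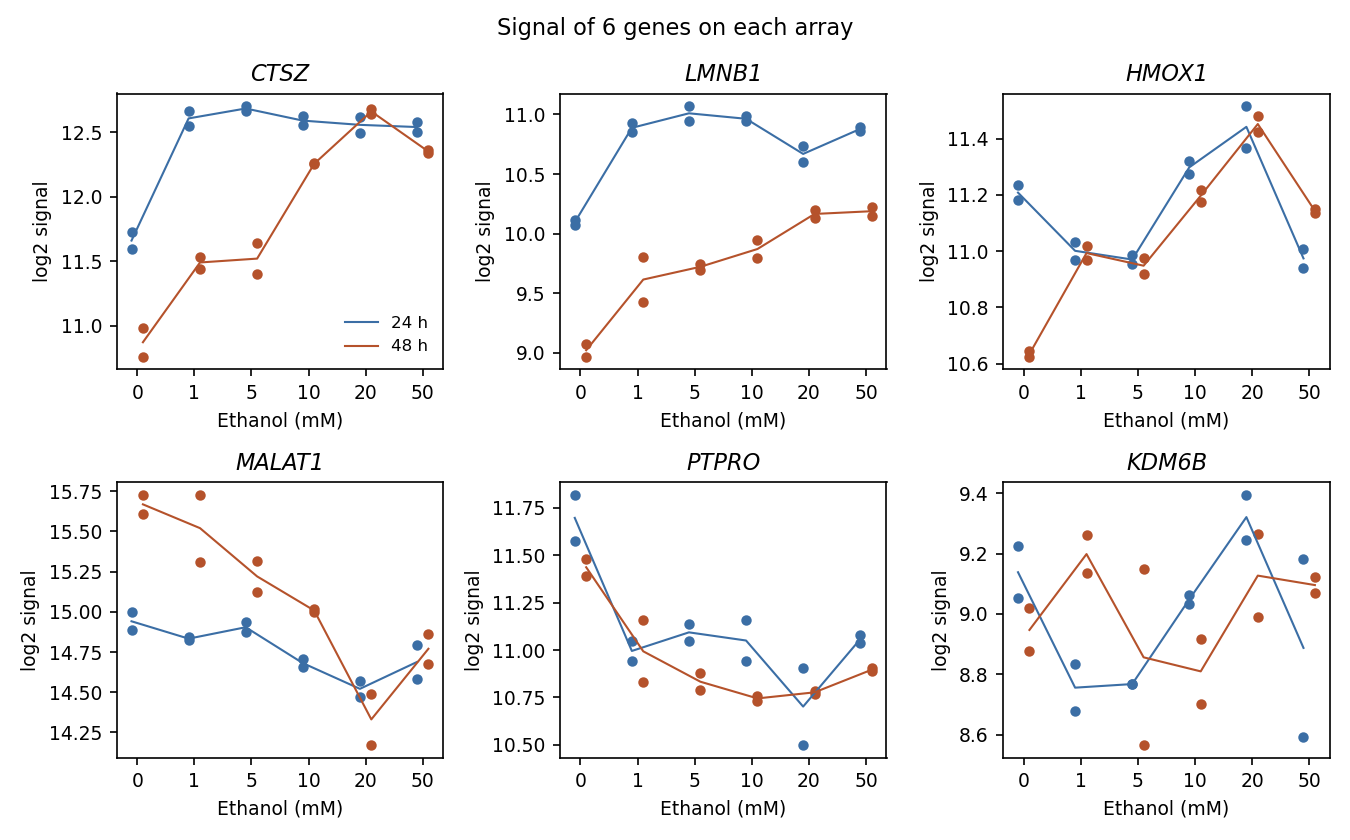
log2 signal (y axis) of 6 genes on each array by ethanol dose (x axis, mM), with 24 h in blue and 48 h in orange; points are the 2 arrays of a group and lines join the group means. CTSZ rose by 1.64 ± 0.07 log2 and MALAT1 fell by 1.17 over the 48 h trend, while KDM6B changed by 0.04 ± 0.15.

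Whether the dose trend differed between the times was tested as the 48 h trend minus the 24 h trend, and 85 genes passed, 35 higher and 50 lower (3 and 11 with median centring). CTSZ had the steeper trend at 48 h, by 1.03 ± 0.10 log2 (SE), as did HMOX1 (0.53 ± 0.08) and MT1H (1.03 ± 0.17). ASNS, PSAT1, CDC27, TRPS1 and MALAT1 had the lower trend at 48 h, with differences of -0.85 ± 0.11, -1.07 ± 0.18, -0.90 ± 0.12, -1.23 ± 0.18 and -0.84 ± 0.14. The difference was negative for LRP1 as well (-0.80 ± 0.13), with trends of 0.84 at 24 h and 0.04 at 48 h. CTSZ, ASNS, CDC27 (-0.28), TRPS1 (-0.71) and LRP1 did not pass with the mean of all probe sets, nor HMOX1 with median centring. LHX8 had the higher trend at 48 h, by 0.40 ± 0.09, but did not pass with median centring or eBayes without a trend. The unfolded protein and integrated stress list was lower at 48 h than at 24 h (median difference -0.19; 4 of 29 lower and none higher, 9 lower adjusted over the list alone; camera adjusted p = 7.823e-07, and adjusted p = 0.0047 with an estimated correlation). The mitotic list was higher (median 0.20; 1 of 32 higher, 5 higher and 1 lower adjusted over the list alone; adjusted p = 2.104e-05, and adjusted p = 0.0126 with an estimated correlation). The DNA replication list was also higher (median 0.10; 1 of 31 higher, 3 adjusted over the list alone; adjusted p = 0.00994, and adjusted p = 0.0359 with an estimated correlation). The replication call ended with the mean of all probe sets (adjusted p = 0.0942). Over the single doses the mitotic list kept 1 direction at neither time. The extracellular matrix list was called lower (median -0.11; 1 of 35 lower, 3 adjusted over the list alone) and the heat shock and oxidative phosphorylation lists higher (medians 0.10 and 0.05; none over all genes, 1 and 3 adjusted over the list alone). These 3 calls, with adjusted p = 2.823e-04, 0.0482 and 0.0404, were lost with an estimated correlation (adjusted p = 0.250, 0.146 and 0.357). The trends of both times shared 9 genes among those that rose, against 0.586 for independent lists, and 6 among those that fell, against 0.119. Without replicate 1 of 50 mM at 48 h 35 genes passed, without its replicate 2 50, without replicate 2 of 50 mM at 24 h 48, and without replicate 1 of 1 mM at 48 h 53. With eBayes without a trend 43 passed and with linear dose scores 150.

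**Figure D4:**
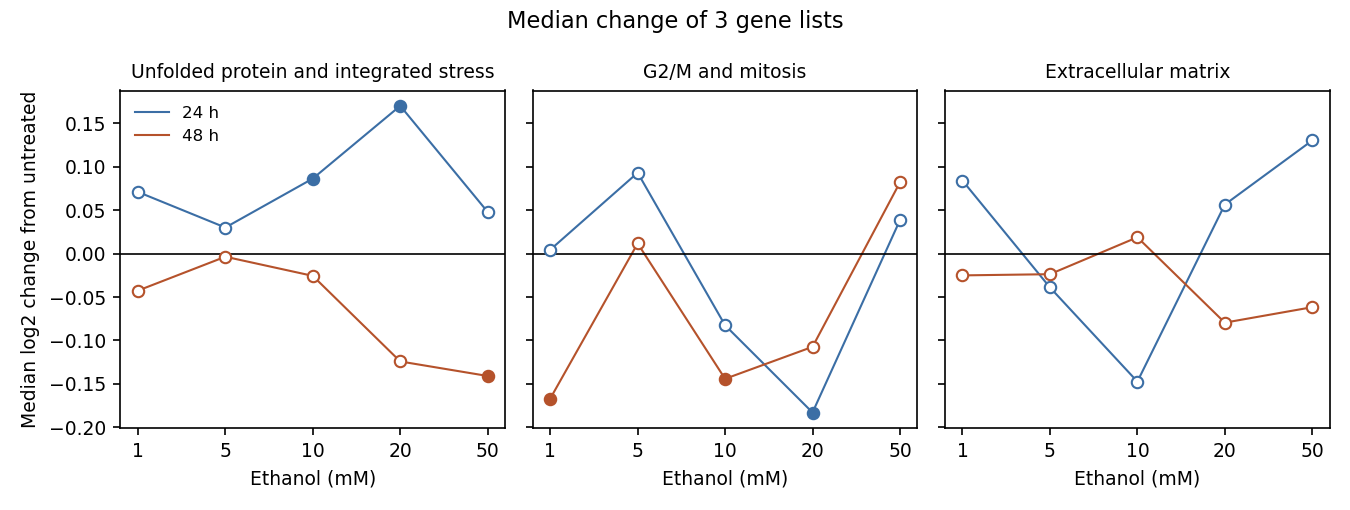
Median log2 change from untreated cells (y axis) of 3 gene lists at each ethanol dose (x axis, mM), at 24 h in blue and 48 h in orange; filled points passed camera with an estimated correlation, open points did not. The unfolded protein and integrated stress list had a median of 0.17 at 20 mM for 24 h and -0.14 at 50 mM for 48 h.

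The mean of the 5 doses against untreated cells, over both times, asked what ethanol did regardless of dose. CTSZ was higher by 1.06 ± 0.05 log2 (SE, 20 treated and 4 untreated arrays), LMNB1 by 0.84 ± 0.06, SYNE2 by 0.66 ± 0.05, FTX by 0.62 ± 0.04, PPP3R1 by 0.59 ± 0.05, ZBTB20 by 0.56 ± 0.04 and JUN by 0.41 ± 0.04. PTPRO fell by 0.65, PSIP1 by 0.52, MALAT1 by 0.46 and the mitochondrial ribosomal protein MRPL32 by 0.40. The histone H3 lysine 4 methyltransferases KMT2A and KMT2D rose by 0.42 ± 0.05 and 0.25 ± 0.05. Of the extracellular matrix genes VCAN, FBN1 and FBN2 rose by 0.26 ± 0.04, 0.18 ± 0.03 and 0.16 ± 0.03. Of the BMP and TGF-beta genes the receptor BMPR2 and the ligand TGFB2 rose by 0.18 ± 0.04 and 0.20 ± 0.05. The 54 very long mRNAs tested had medians of 0.19 at 24 h and 0.05 at 48 h over the 5 doses. Whether a loss of long mRNAs in the untreated arrays adds to the rises of KMT2A, KMT2D and the matrix genes was not tested. In total 132 genes passed, 96 higher and 36 lower (109 and 6 with median centring), and 9 of them by at least 1.5-fold. Of the 38 lists 0 were called by camera with either correlation or by fry, with 3 at an unadjusted p under 0.05 by camera and 6 by fry. The count was 76 without replicate 1 of the untreated cells at 24 h, and 77 and 81 without replicates 1 and 2 of the untreated cells at 48 h. In a model with time and treatment as the only terms 49 genes passed, and calling 20 mM at 24 h and 50 mM at 48 h the untreated groups gave 178. The mean of all probe sets gave 45 genes and eBayes without a trend 82. Of the 18 values named, 8 kept their call with the mean of all probe sets, 2 were not tested and 8 lost it. CTSZ moved to 0.23, KMT2A to 0.11, TGFB2 to 0.02, BMPR2 to 0.07, FBN2 to 0.04, PSIP1 to -0.32 and ZBTB20 to 0.35, and KMT2D was at 0.35 and did not pass. TGFB2 did not pass with eBayes without a trend either.

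The genes around the study's question, histone demethylation, mineralization and ethanol oxidation, mostly did not pass in an ethanol comparison. Of the mineralization genes named earlier, MGP, SLC20A1 and POSTN did pass at 50 mM for 24 h, but SLC20A1 and POSTN not with the mean of all probe sets. The histone H3 lysine 27 demethylase KDM6B changed by -0.25 ± 0.18 log2 at 50 mM for 24 h, 0.15 ± 0.18 at 50 mM for 48 h and 0.04 ± 0.15 over the 48 h trend (SE; adjusted p = 0.615, 0.775 and 0.932 by limma). Within the histone demethylase list KDM3A rose at 50 mM for 48 h, by 0.44 ± 0.11, and KDM2A at 50 mM for 24 h, by 0.32 ± 0.07. With the mean of all their probe sets neither passed, and KDM2A turned to -0.12 (adjusted p = 0.803 by limma). The dentin matrix gene DSPP had a 48 h trend of 1.46 ± 0.41 (adjusted p = 0.0611 by limma), and the osteogenic transcription factor RUNX2 was at 0.25 ± 0.07 at 50 mM for 48 h (adjusted p = 0.0577 by limma). Alkaline phosphatase (ALPL) was at -0.37 ± 0.27 and collagen I (COL1A1) at -0.16 ± 0.09 over the 48 h trend. Aldehyde dehydrogenase 2 (ALDH2), the ethanol-oxidising cytochrome CYP2E1 and catalase (CAT) had 48 h trends of 0.16 ± 0.10, 0.08 ± 0.34 and 0.07 ± 0.05. The endoplasmic reticulum chaperone HSPA5 was at -0.04 ± 0.06, the cytokine IL6 at -0.03 ± 0.13 and the proliferation marker MKI67 at 0.21 ± 0.13, and none of these passed. DMP1, SPP1 and IBSP were not tested.

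Untreated cells at 48 h differed from untreated cells at 24 h in 1785 genes, 919 higher and 866 lower, 151 of them by at least 2-fold. MGP rose by 3.72 ± 0.43 log2 (SE, n = 2 arrays per group), the secreted glycoprotein CHI3L1 by 2.93 ± 0.27, COL21A1 by 2.70 ± 0.47 and KCNQ1OT1 by 1.96 ± 0.34. The kinase PDK4, a brake on pyruvate oxidation, fell by 2.20, and LMNB1 fell by 1.07. Of 32 mitotic genes 30 fell and none rose (32 adjusted over the list alone), including CCNB1 (fell by 1.04), NUSAP1 (fell by 0.99) and TOP2A (fell by 1.07). Of 31 DNA replication genes 11 fell (16 adjusted over the list alone), such as TK1, which fell by 0.89, and 2 of 8 replication-dependent histone genes fell (4 adjusted over the list alone). The extracellular matrix list had 18 of 35 genes rising and 3 falling (21 and 3 adjusted over the list alone), with asporin (ASPN) at 1.28 ± 0.13 and VCAN at 0.72 ± 0.07. The odontogenic and osteogenic list had 9 of 21 rising and none falling (10 and 0 adjusted over the list alone), with POSTN at 0.76 ± 0.06 and ENPP1, which makes the mineralization inhibitor pyrophosphate, at 0.98 ± 0.16. Cholesterol synthesis (4 of 18 rose, 1 fell, the same adjusted over the list alone) and immediate early genes (6 of 24 rose, 8 adjusted over the list alone) were higher, with MSMO1 at 0.70 ± 0.09 and EGR1 at 1.16 ± 0.09. These 7 lists were called by camera with either correlation, with adjusted p = 1.033e-06, 0.00125, 0.0324, 0.0245, 0.0134, 0.0245 and 0.0245 with an estimated correlation, in the order given. A further 7 lists were called with the preset correlation alone. The call of the histone genes ended with no filter (adjusted p = 0.121). CHI3L1 moved to 0.99, ENPP1 to 0.62 and POSTN to 0.91 with the mean of all probe sets, and none of these passed. Without replicates 1 and 2 of the untreated cells at 24 h 1127 and 1186 genes passed, and without replicate 1 of the untreated cells at 48 h 1167. The split turned to 571 higher and 596 lower there, to 455 and 523 with the mean of all probe sets and to 926 and 946 with quantile normalization. Median centring gave 1015 genes.

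Over all doses, 48 h against 24 h gave 4834 genes, 2371 higher and 2463 lower, and 113 of them changed by at least 2-fold. MGP rose by 2.88 ± 0.18 log2 (SE, 12 arrays per time), CHI3L1 by 2.34 ± 0.11, prostaglandin D synthase (PTGDS) by 1.98 ± 0.07 and the secreted protease inhibitor SLPI by 1.90 ± 0.08. The glutathione-degrading enzyme CHAC1 fell by 2.23, and the BMP target genes ID3 and ID1 fell by 1.71 and 1.48, as did the BMP pseudoreceptor BAMBI, by 1.25. All 32 mitotic genes fell, over all genes and adjusted over the list alone, CCNB1 by 1.01 and TOP2A by 1.04, and 22 of 31 DNA replication genes fell (23 adjusted over the list alone). In the unfolded protein and integrated stress list 18 of 29 fell and 3 rose (19 and 3 adjusted over the list alone), with ASNS and PSAT1 falling by 1.21 and 1.23. The mean of all probe sets put ASNS at -0.63, which did not pass, and gave 3159 genes in all, 1415 higher and 1744 lower. Of 17 smooth muscle and pericyte genes 10 fell and 1 rose, the same adjusted over the list alone, with the calponin CNN1 falling by 0.70. Fatty acid synthesis (9 of 13 rose, 10 adjusted over the list alone) included the desaturase SCD at 1.36 ± 0.03. Inflammatory genes (11 of 20 rose, 2 fell, 12 and 2 adjusted over the list alone) included TNFAIP6 at 1.28 ± 0.04 and CCL2 at 0.89 ± 0.04. Of 23 p53 target genes 14 rose and 2 fell (16 and 2 adjusted over the list alone), among them GADD45A at 0.41 ± 0.03. Camera called 14 lists, 12 of them also with an estimated correlation; the homeobox and the oxidative phosphorylation lists were lost (adjusted p = 0.0616 and 0.172 with an estimated correlation).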

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

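The tests of the actin ratio, of the MALAT1 probe sets and of scaling by median centring were chosen after the results they measure had been seen. The list of very long mRNAs was written after the 24 h result but before its own values had been seen, and the other tests before their values.

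The dose trend differed between 48 h and 24 h in 85 genes. Each difference given here is the 48 h trend minus the 24 h trend, on the log2 scale, and each gene named passed by limma. CDH6 had the smallest p, with a difference of -0.71 ± 0.06 (SE), but its probe sets disagreed: the brightest had a 48 h trend of -0.50 and a dimmer one rose by 0.43. CTSZ (1.03), MT1H (1.03), LMNB1 (0.60), MT1X (0.60), IER2 (0.55), HMOX1 (0.53), LHX8 (0.40) and CCNB1 (0.39) had the higher trend at 48 h. SNHG24 (-1.43), ZBED6 (-1.40), TRPS1 (-1.23), PSAT1 (-1.07), CREBRF (-0.97), CDC27 (-0.90), ASNS (-0.85), RASEF (-0.85), MALAT1 (-0.84), LRP1 (-0.80), PMAIP1 (-0.66), MDN1 (-0.64), ZBTB20 (-0.52) and FTX (-0.52, but 0.078 with linear dose scores) had the lower one. Of these 23 genes 8 kept their call with the mean of all probe sets, 2 were not tested and 13 lost it, RASEF at -0.076, PMAIP1 at -0.22 and CDC27 at -0.28 among them, and 12 lost it with median centring. Among the lists that camera called, the median difference was -0.19 for the unfolded protein and integrated stress genes, 0.20 for mitotic genes and 0.10 for DNA replication genes. It was -0.11 for the extracellular matrix, 0.098 for heat shock genes and 0.050 for oxidative phosphorylation, whose calls were lost with an estimated correlation (adjusted p = 0.250, 0.146 and 0.357).

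Probe sets outside the comparisons of named genes also moved with dose. Of 3385 probe sets with no symbol, 292 passed for the 24 h trend (268 higher, 24 lower) and 203 for the 48 h trend (91 and 112). Of the 12178 named genes 42 and 391 passed, and of 1098 probe sets with several symbols 11 and 68. At each dose for 24 h more probe sets with no symbol were higher than lower, 249 and 21 at 5 mM and 347 and 56 at 20 mM. In untreated cells 624 were higher and 100 lower at 48 h than at 24 h. These comparisons share the untreated arrays at 24 h, and the cause was not tested.

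At 24 h 17 genes were higher at every dose, 11 of them with median centring and 3 with the mean of all probe sets. RNA breakdown in the untreated arrays cannot be told apart from an effect of ethanol: at 20 and 50 mM, where the 17 genes had medians of 0.80 and 0.64, the log2 actin ratio lay 0.034 and 0.035 above that of the untreated arrays, within the SEs of 0.106 and 0.038, while at 1, 5 and 10 mM it lay below. Neither can a loss of very long mRNAs: 44 of 54 other very long mRNAs lay above 0, with a median of 0.19 (camera p = 1.301e-07 with an estimated correlation), less than the 0.66 of the 17 genes by more than the SD over the list of 0.18. The doses share both untreated arrays, which keeps this open, and at 48 h, with other untreated arrays, the 17 genes had a median of 0.23 and the other long mRNAs of 0.05. An early effect of ethanol on these genes stays open as a hypothesis. Whether a loss of long mRNAs adds to the rises of other genes named at 24 h, such as those of the matrix, was not tested.

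MALAT1 fell with dose at 48 h. A single faulty probe set is argued against by 11 of 12 probe sets, which were lower with a median of -1.90. A lower yield of nuclear RNA as the whole cause is argued against by the 6 other nuclear noncoding RNAs tested, whose median trend was 0.055 (SD 0.43) against -1.17 for MALAT1. Of the 6, however, 2 fell past the threshold, by 0.50 and 0.61, and FTX rose by 0.49, so a part of the fall may come from such a loss. Ethanol may lower MALAT1, but 8 of 100 orders of the 6 groups gave as many genes as the order of the doses at 48 h, so differences between groups that do not follow dose were not excluded.

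Probe sets other than a gene's brightest fell with dose at 48 h more often than they rose, 744 against 242 of 10635 tested, while the brightest probe sets split 181 against 210. Scaling as the whole source is argued against: 25.7% of those that passed were higher after quantile normalization and 21.1% after median centring, which lowered the count of the brightest probe sets to 123. A loss of signal in all dim probe sets was tested on brightest probe sets with a mean log2 signal of 8.21 or less. Of 3206 tested, 9 passed and 7 of these were higher (77.8%), against 44 of 219 other probe sets (Fisher's exact p = 4.908e-04, two-sided). This met the values set beforehand against such a loss. But 9 are few, probe sets on the same arrays are not independent and each class was adjusted by itself, so the p-value cannot decide. Over all tested in that range the median trend was 0.049, against -0.023 for the other probe sets. A loss of unspliced or nuclear RNA, which such probe sets can read, is a candidate explanation that cannot be told apart here: among probe sets with no symbol 44.8% of those that passed were higher, between the values set beforehand for and against it. No biological explanation was tested.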

How the results depend on the processing

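All alternatives given here were chosen before the data were examined, and none was added later. Quantile normalization, the filter at the 70th percentile, the filter on the highest group mean, the offset and ranks as dose scores kept each of the counts they were run on within 1.5 times, as did the fit to the 4 untreated arrays. Of the 213 named values past the threshold 211 stayed past it, in the same direction, under quantile normalization, 167 under median centring, 205 with no filter and 177 with eBayes without a trend. For the following values the cause was not tested, except that fits to the arrays of 1 time hold fewer arrays and each probe set by itself holds more tests. The centring used the median of all probe sets, a signal of 70.4 to 88.2 that lay near the filter cut. Median centring gave 30 genes at 10 mM and 57 at 20 mM for 24 h, 4, 9, 54 and 63 at 1, 10, 20 and 50 mM for 48 h, 20 and 123 for the trends at 24 and 48 h, 14 for their difference and 1015 for time in untreated cells. With eBayes without a trend the doses in rising order gave 30, 49, 44, 99 and 36 at 24 h, and 1, 10, 20 and 50 mM gave 3, 12, 71 and 122 at 48 h. The trends gave 25 and 254, their difference 43 and the mean of the 5 doses 82. The mean of all probe sets gave 12, 22, 16, 97 and 20 at 24 h, 8 at 10 mM for 48 h, 21 for the 24 h trend, 45 for the mean of the 5 doses, 978 and 3159 for time in untreated cells and over all doses, and left 105 of the 213 named values past the threshold, with 87 lost and 21 not tested. It also reversed AHNAK at 1, 5 and 50 mM for 24 h (-1.24, -0.0043 and -0.21), CTSZ at 50 mM for 24 h (-0.053) and 1 mM for 48 h (-0.021). It reversed KDM2A at 50 mM for 24 h (-0.12), MACF1 at 1 mM for 24 h (-0.025), CDH6 in the 48 h trend (0.17) and the median of the smooth muscle list at 50 mM for 48 h (0.054). It ended or turned 18 of 63 list calls named, 3 of which had passed with an estimated correlation. Of the 63 list calls median centring ended 9, each probe set by itself 10, eBayes without a trend 7 and the filter at the 70th percentile 6. Under quantile normalization 5 ended and 1 turned. Quantile normalization reversed the median of the ribosomal protein list at 10 mM for 24 h (0.0093), and leaving out 1 array moved that of the mitotic list at 20 mM for 48 h between -0.14 and 1.841e-04. Each probe set by itself gave 122, 192, 144, 532 and 126 at 24 h, 20, 20, 33, 636 and 959 at 48 h, 153 and 1361 for the trends, 371 for their difference, 336 for the mean of the 5 doses, and 3114 and 8503 for time. Array weights gave 150 at 10 mM and 103 at 20 mM for 24 h, no filter gave 68 at 5 mM for 24 h, and linear dose scores gave 7 for the 24 h trend and 150 for the difference, and reversed the difference of FTX (0.078). Only the arrays of 24 h gave 32, 45, 37, 91 and 42 and a trend of 23, and only those of 48 h gave 1, 3, 8 and 138 at 1, 5, 10 and 50 mM. Of the 41 list calls in the main comparisons 21 passed with an estimated correlation, and fry called 80. With the replicate number as a replicate block, 379 genes passed for the 48 h trend, 40 for the 24 h trend and 208 of the named values. No count moved by over 1.5 times, and the differences between replicates 1 and 2 correlated between -0.11 and 0.089 over 66 pairs of groups, so the numbers do not pair the arrays. Leaving out each array in turn, where a lone array is assumed to vary like the other groups, gave ranges of 29 to 65, 37 to 129, 26 to 88, 78 to 238 and 20 to 103 at 24 h. At 48 h the ranges were 7 to 17, 5 to 18, 19 to 22, 70 to 128 and 62 to 244. They were 22 to 68 and 155 to 412 for the trends, 35 to 108 for their difference, 76 to 140 for the mean of the 5 doses, 1127 to 1834 and 4540 to 4771 for time, 37 to 46 lists and 179 to 213 named values. Detection calls were not used here, so whether a dim gene lay above background is known only from its signal.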

Other observations

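The splits and orders in this part were set before their counts were seen, and the genes of the first paragraphs were chosen after their values were seen.

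Signalling and metabolic genes outside the lists described so far also moved with time in culture, 48 h against 24 h over all doses (log2, SE over 12 arrays per time, all passing by limma). Of 23 WNT genes 10 rose and 8 fell. The WNT antagonists FRZB and SFRP4 rose by 1.18 ± 0.13 and 0.83 ± 0.06 and the ligand WNT2B by 0.65 ± 0.04, while the antagonist DKK1 fell by 0.40 and the receptor FZD4 by 0.73. Of 28 BMP and TGF-beta genes 7 rose and 12 fell: the ligand BMP4 rose by 0.66 ± 0.06, and TGFB2 fell by 0.65. Among 18 craniofacial homeobox genes and their partners 8 rose and 3 fell, with PRRX1, SIX2, LHX8 and PAX9 at 0.55 ± 0.03, 0.72 ± 0.05, 0.44 ± 0.03 and 0.32 ± 0.03, while PRRX2 fell by 0.45.

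Of 15 surface markers and niche factors of mesenchymal stem cells 6 rose and 5 fell. The chemokine CXCL12 and the adhesion molecule VCAM1 rose by 0.54 ± 0.03 and 0.43 ± 0.03, and the pericyte marker MCAM fell by 0.75, NT5E (CD73) by 0.35 and THY1 (CD90) by 0.20, which did not pass with the mean of all probe sets. The metallothioneins MT1X and MT2A fell by 1.23 and 1.02, and superoxide dismutase 2 (SOD2) rose by 0.56 ± 0.05. In the methionine and folate cycle 2 of 15 genes rose and 6 fell, with MTHFD2 and CBS falling by 0.68 and 0.61. The WNT, BMP, stem cell surface and folate lists were not called by camera (adjusted p = 0.517, 0.0509, 0.758 and 0.248), and the homeobox call was lost with an estimated correlation (adjusted p = 0.0616).

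Fold changes of different doses against the same untreated arrays correlated across genes at a mean of r = 0.521 at 24 h and 0.493 at 48 h, where simulated unchanged groups gave 0.4998. Genes are not independent replicates. The mean covariance was 0.0436 and 0.0371, against 0.0297 simulated, and between the times the correlations lay between -0.068 and 0.077.

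In a model with time and treatment as the only terms, 49 genes differed between treated and untreated arrays. When single arrays were reassigned, 1 of 100 splits, the real one, gave as many, and the highest other gave 2. Such random splits mostly part the 2 arrays of a group. They therefore cannot tell an effect of ethanol from chance differences between whole groups. When the 2 arrays of a group were kept together, 2 of 36 choices of 1 group per time gave as many, the real one and 20 mM at 24 h with 50 mM at 48 h, which gave 178. Chance differences between whole groups were therefore not excluded. For 48 h against 24 h, 4304 genes differed in the same way of counting, and 1 of 100 splits gave as many, of single arrays or of whole groups. The highest other splits gave 1595 and 2160, so chance among such groupings is argued against. Any difference in harvest or hybridisation between the times could not be told apart from time in culture. Of 100 orders of the 6 groups at 24 h, 56 gave at least the 42 genes of the dose trend, and the highest other order gave 356. At 48 h 8 of 100 gave at least 391, and the highest other gave 414. For neither time was a difference between groups that ignores the order of the doses excluded.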
